A study of Mus musculus with 672 samples.

How the data were processed

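The series holds 672 single mouse cells (strain C57BL/6) from embryonic pancreas, sequenced with a full-length method of the Smart-seq2 kind and Nextera XT libraries on an Illumina HiSeq. Cells were sorted after antibody staining, 1 cell per well, into 7 plates of 96 wells. Per the labels, 4 plates hold cells of embryonic day (E) 13.25 and carry pancreas numbers 1 to 4. Titles of pancreas 4 carry a second mouse number that those of 1 to 3 lack, so plates 1 to 3 may share a source that plate 4 does not, and the 4 plates may not be 4 independent samples. The other 3 plates hold cells of E15.25: tip of bud 1, tip of bud 2 and trunk of bud 2. They are called here E15.25 tip 1, tip 2 and trunk 2. Tip 2 and trunk 2 carry the same bud number, so the 3 E15.25 plates come from 2 buds by the labels and n = 3 may overstate the independent samples. The antibodies and the sort gates are not given. The plate is the replicate in the comparisons of ages, regions and classes. The labels do not say that the plates come from separate embryos, so their p-values measure only the spread between plates, which may be technical. The tests of well position permute wells or cells within a plate, and their p-values measure the spread between those. The protocol text attached to the E15.25 cells speaks of E13.25 embryos, and the ages used are those of the age labels.

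The deposited files hold raw read counts per gene, made by the authors with GSNAP 2015-09-29 and HTSeq 0.5.3p3 on mm10, with no normalization. They cover 46078 Ensembl genes, 92 ERCC spike-in transcripts and 5 HTSeq classes of reads without a gene. Symbols came from the reference annotation, which named 45143 genes. There were no molecular identifiers, so reads are not independent molecules, and intervals and floors cover counting error only. The annotation release, the strand setting and the handling of reads with several positions are not stated. Values of near-identical paralogs (Prss1, Prss2 and Prss3, Try4, Try10 and Gm5771, Amy2b, Serpina1b and Serpina1e, Ins1 and Ins2, the globins) can hold reads of one another.

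A cell was kept with at least 100000 reads on genes, at least 1500 genes with a read and at most 20% of reads on mitochondrially encoded genes. Of the wells, 68 lay under the read minimum, 11 under the gene minimum and 4 over the mitochondrial limit, and a well can fail more than 1 of these. No doublet caller was run, since each well received 1 sorted cell. An alternative leaves out the 5% of cells of each plate with the most genes. Cells were clustered within each age with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes without the cell cycle lists, 15 principal components, 10 neighbours, resolution 1, seed 1). Clusters were named from marker sets of 12 classes. A marker passed with at least 2 times the CPM of the other cells of the age, after adding 5 CPM, and over 10 CPM in at least 25% of the cluster. A name needed at least 3 passing markers and a share of passing markers at least 2 times that of the next class. Endocrine progenitor-like and endocrine-like cells were joined as endocrine-lineage-like. The markers and the omission of the cell cycle lists were fixed beforehand, but the other clustering settings and the naming rule were set after seeing the data, before any gene was tested between ages. A clustering that also left out genes correlated with the cell cycle was tried and dropped, because it merged mesothelium-like with acinar or tip-like cells of E15.25. A first naming rule, a minimum share of the markers of a class, was then replaced by the ratio above. It would have left unnamed a cluster of 20 cells of E13.25, which the ratio names mesenchyme-like. Under the ratio 2 clusters of E15.25 (13 cells, all in tip 2, and 9 cells, all in trunk 2) stay unnamed, and no cluster of E13.25 does.

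Raw counts of the kept cells were summed per plate, and per plate and class with at least 10 cells. Sums were compared with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The age comparison set the 4 E13.25 plates against the 3 E15.25 plates. Tip, trunk and E13.25 were compared in a fit of 3 groups, in which the single trunk plate is assumed to vary like the other groups. No paired analysis was possible for the ages because the pancreas and bud numbers name different embryonic stages, nor for tip and trunk, which share bud 2 alone. The age comparisons in acinar or tip-like and trunk or duct-like cells used the same test. In endocrine-lineage-like cells neither age had 2 plates with 10 cells, so the fit with at least 5 cells, chosen before the data were seen, is reported. The comparison in mesenchyme-like cells was chosen after seeing the data. The fits were tested on simulated data with 200 changed genes each, and the recovered shares stand with the limits of the results. The changed genes were drawn only from genes above a minimum of expected reads, so the shares do not cover genes with few reads.

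Lists of genes fixed beforehand were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry beside it. There were 20 such lists: digestive enzymes, acinar and tip transcription factors, trunk and duct genes, Neurog3 cascade, endocrine hormones and secretory granule, endocrine transcription factors, Notch pathway, S phase, G2/M phase, ER stress and secretory pathway, immediate early and dissociation, glycolysis and hypoxia, pancreatic epithelium, mesenchyme, mesothelium, endothelium, erythroid, leukocyte, neural crest and neuron, and gut and liver epithelium. Ribosomal protein genes and mitochondrially encoded genes made 2 further lists. Cell cycle lists were compared between classes with plate as a block.

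The comparisons, their tests, the cell and gene filters, the gene lists, the markers and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest changes in each direction among genes past the threshold with a mean of at least 10 CPM and plates that did not overlap between groups. It added up to 4 members of each list past the threshold and 26 lead genes whatever they showed. Some genes that the rule names are not reported here. A fold against a group with 0 reads was computed against a floor of 3 reads over the group and is given as a lower bound. With 1 to 3 reads the ratio is given with its 95% counting interval.

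A gene was detected in a cell with at least 3 reads after thinning each cell to 100000 reads. Shares of cells per plate were compared with a two-sided exact permutation test over the 35 arrangements of 4 and 3 plates, which cannot give a p below 0.0286. Shares of 21 genes or gene pairs and of the classes were each adjusted by Benjamini-Hochberg. Intervals of single plates are exact (Clopper-Pearson) at 95%, and the limit for a share of 0 is 3 cells of the total.

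After the data were seen, reads of a gene in wells that share a row or a column with a strong source were measured. The position of a well was inferred from its number, counted down columns of 8, since the labels give none. This layout was taken because reads of strong genes follow it, so the tests of position are not independent of that choice. Rates were taken from 15 hormone and globin genes. A cell with reads over 3 times those expected from its row and column was then required as an alternative, and the expected reads were subtracted as another. A term for plates with under 40% of reads not aligned was also chosen after seeing the data.

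Other settings chosen before the data were seen were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no filter on low counts, each cell scaled to the same total, at least 3000 genes per cell, the omission of the cells with the most genes, other groupings of plates, at least 5 cells of a class, other detection minimums, cluster resolutions of 0.5 and 2, no plate block, and each plate left out in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.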

Results

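After the filters 601 cells remained, 340 of E13.25 and 261 of E15.25. The E13.25 plates 1 to 4 kept 88, 80, 86 and 86 cells, and E15.25 tip 1, tip 2 and trunk 2 kept 87, 85 and 89. Kept reads on genes ran from 95215056 in E15.25 tip 2 to 157638042 in E13.25 plate 3. The median cell had between 773545 reads (E15.25 trunk 2) and 1526821 reads (E13.25 plate 2), and the median number of genes with a read lay between 8171 and 9313. The median share of reads not aligned was 33.6%, 34.2% and 28% in E13.25 plates 1 to 3, 50.2% in E13.25 plate 4, and 47.3%, 51.3% and 47.1% in the E15.25 plates. The share of reads on ERCC spike-ins was 2.61% in E13.25 plate 1 and between 15.1% and 27.3% in the other plates. The median share of reads on mitochondrially encoded genes separated the ages. It was between 3.426% and 4.233% in the E13.25 plates and between 5.122% and 5.771% in the E15.25 plates, so cell quality may differ between the ages.

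The series sets E15.25 against E13.25. The labels name no region for the E13.25 plates, while every E15.25 plate is tip or trunk. Age and the part sampled therefore cannot be fully told apart in any comparison of the ages. Over whole plates 141 of 20728 genes differed between these ages, 97 higher and 44 lower at E15.25 (edgeR). The DESeq2 Wald test called 1003 higher and 1151 lower, so the balance of directions depends on the test. Most of the named genes with the largest increases encode pancreatic digestive enzymes, which acinar cells secrete. Prss3, a trypsinogen gene, had 0 reads in the 4 E13.25 plates and 126 ± 50.5 CPM (SD, n = 3) at E15.25, at least 19800-fold higher. Try10, another trypsinogen gene, went from 0.0304 ± 0.00924 CPM (n = 4) to 414 ± 162 CPM (n = 3). Prss1, Gm5771, Try4, Amy2b and Cela3b, all trypsinogen, amylase or elastase genes, rose by between 6.31 and 13.09 on the log2 scale. Pnliprp1, a lipase-related gene, rose from 976 ± 496 to 22150 ± 7783 CPM (log2 change 4.51, SE 0.453, adjusted p = 0.0134). Aqp8, a water channel, had 2 reads in the E13.25 plates, and its ratio was 12500 (counting interval 3450 to 103000). Pdia2, a pancreatic protein disulfide isomerase, also had 2 reads there, with a ratio of 6450 (1780 to 53200). The adenosine receptor gene Adora1 rose as well, with a log2 change of 8.28 (adjusted p = 0.021).

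Among 30 measured digestive enzyme genes 14 rose and none fell, and 26 rose when adjusted over the list alone. The list kept its call with an estimated correlation (camera, adjusted p = 0.0108), the only one of the 22 lists to do so in whole plates. Bhlha15 and Rbpjl, transcription factors of acinar cells, rose by 3.45 and 2.05 on the log2 scale, 2 of 11 members of their list (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.184 with an estimated correlation). Ptf1a, which is needed for acinar fate, had 35.7 ± 16 CPM at E13.25 and 156 ± 78.2 CPM at E15.25 without passing the threshold (adjusted p = 0.0851). Cpa1, a carboxypeptidase gene used as a marker of tip cells, had 1832 ± 1196 and 7445 ± 3658 CPM (adjusted p = 0.112). In the list of trunk and duct genes 2 of 19 rose, Clu from 282 ± 124 to 2607 ± 246 CPM and Pkhd1 by 1.89 on the log2 scale (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.244 with an estimated correlation). Spp1, Sox9 and Nkx6-1, genes of the trunk, did not pass the threshold, with log2 changes of 1.65, -0.74 and -1.08.

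Genes lower at E15.25 included Sox11 and Sox4, transcription factors of immature cells, with log2 changes of -2.88 and -1.85. Hey1, a target of Notch signalling, had a log2 change of -2.93 (35.5 ± 9.34 CPM at E13.25, 4.64 ± 2.53 CPM at E15.25, adjusted p = 0.0429). It was the only one of 18 Notch pathway genes to fall (1 rose and 5 fell adjusted over the list alone), and the list lost its call with an estimated correlation (adjusted p = 0.184). In the list of the Neurog3 cascade Sox4 alone of 22 genes fell (3 fell adjusted over the list alone; adjusted p = 0.226 with an estimated correlation). Neurog3 itself, which starts the endocrine programme, had 314 ± 129 CPM at E13.25 and 135 ± 55 CPM at E15.25 (adjusted p = 0.19). Serpina1b and Serpina1e, alpha-1-antitrypsin genes, had log2 changes of -4.75 and -4.70. Fsd1, Scube3, Gm42992, Plppr3, Gm266 and Gng2 fell too, by between 2.53 and 3.28 on the log2 scale.

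Of 20 measured immediate early genes, which answer stimuli and tissue dissociation within minutes, 3 rose: Btg2 from 289 ± 82.3 to 1514 ± 279 CPM, Egr2 from 43.7 ± 16.9 to 276 ± 86.9 CPM and Fos from 845 ± 211 to 2879 ± 950 CPM. Adjusted over the list alone 12 rose, and the adjusted p was 0.184 with an estimated correlation. In the list of ER stress and secretory pathway genes 2 of 29 rose, Sel1l (log2 change 1.55) and Herpud1 (1.56), both parts of the degradation of misfolded proteins in the endoplasmic reticulum. Adjusted over the list alone 16 rose (adjusted p = 0.184 with an estimated correlation). In the list of glycolysis and hypoxia 1 of 22 rose, Car9, a carbonic anhydrase gene induced by low oxygen (log2 change 3.08; 3 rose adjusted over the list alone; adjusted p = 0.184 with an estimated correlation).

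The other lists gave few or no genes past the threshold in whole plates. Among 21 endocrine hormone and granule genes none passed in the main edgeR fit (3 rose adjusted over the list alone, and adjusted p = 0.324 with an estimated correlation). Nor did any of 15 endocrine transcription factors (adjusted p = 0.967). The hormone gene Ins2 passed in another setting of the processing. S phase and G2/M phase lists had no member past the threshold, with 2 of 42 G2/M genes higher when adjusted over the list alone (adjusted p = 0.847 and 0.324 with an estimated correlation). The pancreatic epithelium list had 1 of 20 lower, Sox11 (adjusted p = 0.873). Lists for other cell types had no member past the threshold over all genes tested, with an adjusted p of 0.967 for mesenchyme, 0.761 for mesothelium, 0.858 for endothelium, 0.858 for erythroid cells, 0.967 for leukocytes, 0.847 for neural crest and neurons and 0.872 for gut and liver epithelium with an estimated correlation. Ribosomal protein genes and mitochondrially encoded genes had none past the threshold either (adjusted p = 0.987 and 0.324). Adjusted over the list alone 2 mesenchyme genes rose and 2 fell, 1 leukocyte gene rose, 1 neural gene rose and 2 fell, 2 gut and liver genes fell and 3 mitochondrially encoded genes rose. For endocrine transcription factors, leukocyte genes, gut and liver genes and ribosomal protein genes the median change and the direction of camera differed in sign, and for mesenchyme genes the mean and the median did.

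The count of 141 moved with the plates. Without E13.25 plates 1 to 4 in turn it was 28, 37, 35 and 63, and without E15.25 tip 1, tip 2 and trunk 2 it was 11, 20 and 19. A term for the plates with under 40% of reads not aligned, E13.25 plates 1 to 3, left 1 gene. Age then rests on E13.25 plate 4 alone at the earlier stage. Whether this or the batch ended the calls was not tested. On simulated data this fit recovered 26.9% of 4-fold and 56.1% of 8-fold changes.

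**Figure D1:**
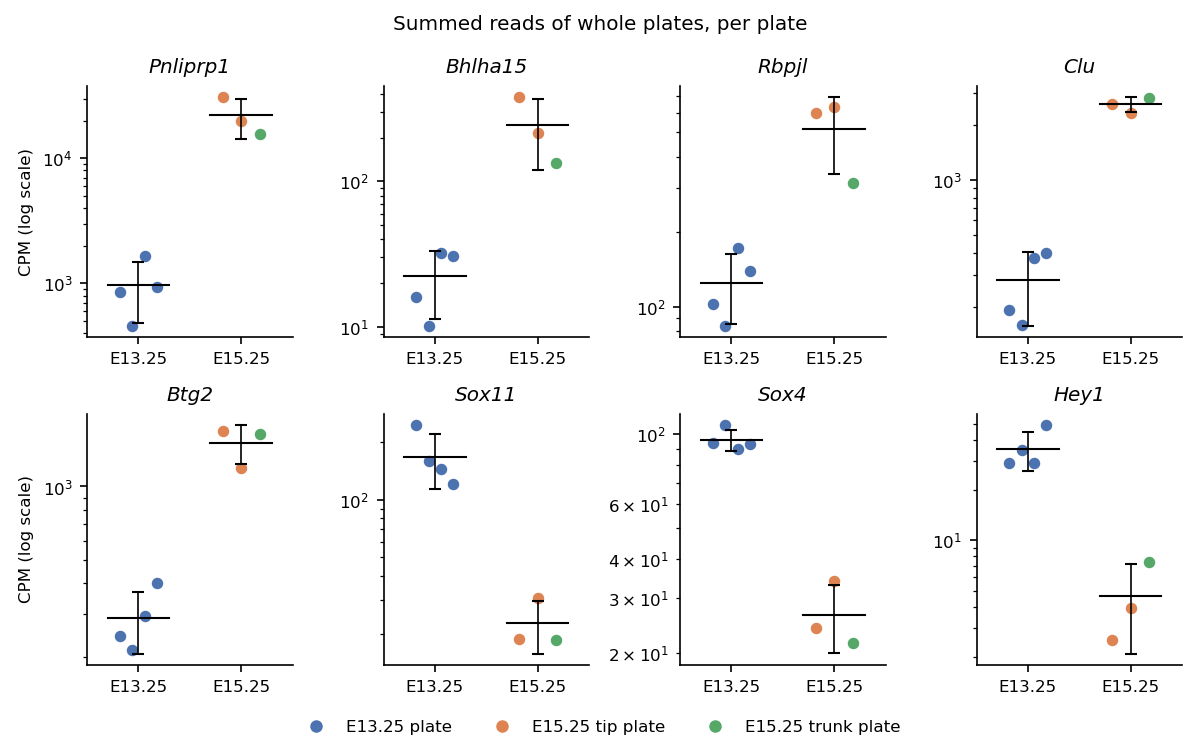
CPM (log axis) of 8 named genes in the summed reads of each plate, with 4 E13.25 plates on the left and 3 E15.25 plates on the right of each panel; lines give means and bars the SD. Pnliprp1 averaged 976 CPM at E13.25 and 22150 CPM at E15.25, and Sox4 fell from 95.8 to 26.6 CPM.

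The labels split the E15.25 cells into tip, where acinar cells form, and trunk, where duct and endocrine cells form. Against E13.25 the 2 tip plates had 19 genes higher and none lower (25432 tested, edgeR). The DESeq2 Wald test called 915 higher and 1304 lower, and with each cell scaled to the same total 71 were higher and 17 lower. The 19 genes included Prss3 (at least 15100-fold higher), Try10, Prss1, Prss2 and Pnliprp1, and the water channel gene Aqp8 (ratio 15000, counting interval 4140 to 124000). Aldh1a1, which makes retinoic acid, rose from 3.03 ± 0.414 CPM (n = 4) to 52.2 ± 4.06 CPM (n = 2). The metallothionein gene Mt1 rose by 3.70, the glutathione transferase gene Gstm1 by 3.25, Car9 by 3.12 and Sel1l by 1.66 on the log2 scale. Of 30 digestive enzyme genes 5 rose, and 25 when adjusted over the list alone (adjusted p = 0.0495 with an estimated correlation). The count was 2, 10 and 6 without E13.25 plates 1, 2 and 3, and 202 without tip 1 and 5 without tip 2. On simulated data 10.4% of 4-fold and 42.4% of 8-fold changes were recovered.

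In edgeR all genes past the threshold in the trunk plate against E13.25 were higher. The DESeq2 Wald test called more genes lower than higher there. With n = 1 these calls rest on the spread between plates of the other groups, and on simulated data this fit recovered 7.6% of 8-fold changes. Trypsinogen genes were among them here too, with Prss3 at least 29100-fold higher and Try10 at 392 CPM (n = 1) against 0.0305 ± 0.00932 CPM (n = 4). Aldoc, a glycolytic aldolase gene, rose by 4.16, Gas2 by 3.11, Gstm1 by 2.65 and the protease gene Adamts9 by 2.41 on the log2 scale. Of 30 digestive enzyme genes 3 rose, and 20 when adjusted over the list alone (adjusted p = 0.0224 with an estimated correlation). Hes1 and Spp1, genes of trunk cells, did not pass the threshold, with log2 changes of 1.28 and 2.10. Fewer genes passed the threshold without each of the other plates in turn, and in a fit of these 2 groups alone.

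Tip against trunk gave 0 genes past the threshold in edgeR, with 1208 at an unadjusted p under 0.05, while the DESeq2 Wald test called 338. None of 20 measured trunk and duct genes passed, with 2 of 20 log2 differences positive (adjusted p = 0.693 with an estimated correlation). Sox9 and Hes1 had log2 differences of -1.15 and -0.997 (adjusted p = 0.931 for both), and the acinar factor Rbpjl had 613 ± 17.5 CPM (n = 2) in tip and 313 CPM (n = 1) in trunk. Of 30 digestive enzyme genes 25 had a positive log2 difference, none past the threshold (adjusted p = 0.693 with an estimated correlation). The single trunk plate limits this comparison: on simulated data it recovered none of the 8-fold changes.

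Within acinar or tip-like cells the age comparison asks which changes remain when the shares of the classes are set aside. The mix inside the class can still differ. Over all plates it is a cluster of 48 cells at E13.25 and clusters of 37 and 42 cells at E15.25. Trunk or duct-like cells are clusters of 55 and 21 cells at E13.25 and one of 39 at E15.25. The markers that name the clusters within each age include genes reported here, such as Pnliprp1 and Bhlha15. The comparison in acinar or tip-like cells called 110 of 15474 genes, 74 higher and 36 lower at E15.25 (E13.25 plates 3 and 4, 3 E15.25 plates). Digestive enzymes rose within these cells as well, 11 of 30 and 23 when adjusted over the list alone (adjusted p = 0.0479 with an estimated correlation). Pnliprp1 rose from 4106 ± 823 CPM (n = 2) to 53990 ± 4939 CPM (n = 3). Prss3, Aqp8, the water channel gene Aqp12, the zymogen granule gene Zg16 and the chymotrypsin gene Ctrc had 0 reads at E13.25 and were at least 6100-fold, 3060-fold, 1110-fold, 604-fold and 378-fold higher at E15.25. For Ctrc this holds for E13.25 plates 3 and 4 alone, since its log2 change was 2.25 (adjusted p = 0.634) with at least 5 cells per plate. Try10, Prss1, Slc26a9 and Liph rose by between 9.74 and 13.01 on the log2 scale, and Pdia2 had a ratio of 2250 (counting interval 622 to 18600). Bhlha15 rose by 2.48 on the log2 scale, the only one of 11 acinar transcription factors past the threshold (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.151 with an estimated correlation).

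Genes lower at E15.25 in acinar or tip-like cells included the actin bundling gene Fscn1 (79.1 ± 1.91 CPM, n = 2, against 0.581 ± 0.262 CPM, n = 3), Rimklb, Akr1cl, the connexin gene Gjc1, Rem2, Cand2, Dbn1 and Serpinf1, with log2 changes between -7.14 and -4.76. Vim, an intermediate filament gene of mesenchymal and immature cells, had a log2 change of -2.80, Igfbp5 one of -3.87 and the fetal liver gene Afp one of -2.15. Prox1 (-1.61) and the tight junction gene Cldn6 (-2.01), both of the pancreatic epithelium list, were lower, while the keratin gene Krt18 rose by 1.75. Dlk1, of the Notch pathway list, had a log2 change of -1.97. Nkx6-1, a factor of the trunk and of early progenitors, had 98.7 ± 45.8 CPM (n = 2) at E13.25 and 17.3 ± 4.35 CPM (n = 3) at E15.25 without passing the threshold (adjusted p = 0.0728). Sox9 had a log2 change of -1.60 (adjusted p = 0.146).

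In these cells 5 of 20 immediate early genes rose, and 15 when adjusted over the list alone (adjusted p = 0.151 with an estimated correlation). Egr2 rose by 5.63, Btg2 by 4.07, Fos by 3.14 and Egr1 by 2.84 on the log2 scale. Clu, Sel1l and Car9 rose too, by 2.18, 2.45 and 2.89. The collagen gene Col3a1 rose from 1.18 ± 0.0141 to 45.6 ± 6.67 CPM and Dcn from 0.140 ± 0.0408 to 14.1 ± 1.81 CPM. With reads expected from other wells subtracted both lost their call as the spread grew, with log2 changes of 5.27 (SE 0.514 before, 1.5 after) for Col3a1 and 5.89 (SE 1.63, from 6.60, SE 0.922) for Dcn, which leaves the source of their reads open. The count of 110 was 31 and 27 without E13.25 plates 3 and 4, 1, 9 and 6 without E15.25 tip 1, tip 2 and trunk 2, and 14 without the 5% of cells with the most genes. Simulated 4-fold and 8-fold changes were recovered in 17.9% and 42.4% of genes.

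Within trunk or duct-like cells 31 of 14883 genes differed in edgeR, 24 higher and 7 lower at E15.25 (4 against 3 plates). The DESeq2 Wald test called 354 higher and 393 lower. The list of trunk and duct genes rose, with 5 of 19 members past the threshold (10 rose and 3 fell adjusted over the list alone; adjusted p = 0.0374 with an estimated correlation). Spp1, the osteopontin gene, rose from 8567 ± 1058 to 19290 ± 1677 CPM (adjusted p = 0.0205). Clu rose by 3.06, the ciliary gene Dcdc2a by 1.79 and the RNA-binding gene Bicc1 by 1.91 on the log2 scale. Metallothionein genes Mt1 and Mt2 rose by 3.29 and 2.71, the interferon factor gene Irf1 by 4.40, Mcam by 2.96, the serine synthesis gene Psat1 by 2.55, Matn2 by 2.36 and Krt18 by 1.37. Ptgs1 and Sod3 rose as well, with adjusted p = 0.046 and 0.0476.

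Id3, an inhibitor of differentiation factors, had 322 ± 145 CPM (n = 4) at E13.25 and 3.63 ± 1.63 CPM (n = 3) at E15.25 in trunk or duct-like cells. Parm1, Igfbp4, the cartilage collagen gene Col2a1 and the growth factor gene Mdk had log2 changes of -2.86, -2.26, -1.80 and -1.75. Gm266 and Scn2b were down to 2 and 3 reads at E15.25, with E13.25 to E15.25 ratios of 1020 (counting interval 282 to 8410) and 429 (147 to 2080). Amy2b and Iapp, an acinar and an endocrine gene, had 2 reads and 1 read at E13.25 and ratios of 3260 (903 to 26900) and 2700 (485 to 107000). Exchange between wells predicts 173, 338 and 222 of the 287, 2116 and 278 Amy2b reads in these cells of E15.25 tip 1, tip 2 and trunk 2, and with the expected reads subtracted both genes lost their call at fitted log2 changes of 11.13 (SE 1.87) for Amy2b and 9.77 (SE 1.56) for Iapp, against 11.50 (SE 1.54) and 10.95 (SE 1.5) before. The source of the remaining reads is open. Nkx6-1 and Sox9 did not pass the threshold, with log2 changes of -1.37 (adjusted p = 0.0879) and -1.09. The count of 31 was 2, 10, 1 and 14 without E13.25 plates 1 to 4, 0, 12 and 0 without E15.25 tip 1, tip 2 and trunk 2, and 0 with the term for reads not aligned. The fit recovered 22.4% of simulated 4-fold and 42.4% of 8-fold changes.

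In endocrine-lineage-like cells hormone genes had higher values at E15.25, none past the threshold in the main edgeR fit (3 E13.25 and 2 E15.25 plates, at least 5 cells each). Gcg, Ins1, Ins2 and Sst passed in another setting of the processing, and so did the rise of Mki67 and the fall of Neurog3. On simulated data the main fit recovered 0% of 4-fold and 9.1% of 8-fold changes, so few changes could be called. Gcg, the glucagon gene, had 9.99 ± 17.3 CPM (n = 3) and 6830 ± 5070 CPM (n = 2), and Ins2, an insulin gene, had 8.24 ± 13.4 and 17230 ± 24050 CPM. Sst, the somatostatin gene, had 0 reads at E13.25 and 700 ± 700 CPM at E15.25, at least 5290-fold higher (adjusted p = 0.433). Of 24 endocrine hormone and granule genes 10 rose when adjusted over the list alone (adjusted p = 0.074 with an estimated correlation). Neurog3 had 3237 ± 1782 CPM at E13.25 and 561 ± 691 CPM at E15.25 (adjusted p = 0.644), and Pax4 had 676 ± 176 and 274 ± 273 CPM. The only gene called among 14465 was Pnliprp1, an acinar enzyme gene (3.74 ± 1.22 and 604 ± 84.9 CPM), and it lost its call without each of the 5 plates in turn. With reads expected from other wells subtracted it lost its call too, with a log2 change of 7.30 (SE 0.899) against 7.33 (SE 0.496), so the call ended with the spread and exchange between wells predicts 0.818 and 0.852 times its reads in these cells of tip 2 and trunk 2. The source of the rest is open.

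Shares of cells with a gene detected followed the enzymes and hormones, but no share passed the threshold after adjustment over 21 genes and pairs. The smallest possible p of 0.0286 passes such an adjustment only when many shares reach it together. Little could therefore pass here, among the shares within a class or among the class shares. Cells with Ptf1a made up 11.7% ± 6.76 (SD, n = 4) at E13.25 and 43.3% ± 7.34 (n = 3) at E15.25 (exact permutation p = 0.0286, adjusted p = 0.15). The share with Cpa1 was 37.1% ± 14.9 and 96.6% ± 1.10, and that with the proliferation gene Mki67 30.7% ± 12.6 and 54% ± 1.99. Cells with the epithelial gene Epcam made up 47.9% ± 21 and 80.04% ± 4.20, and those with Cpa1 together with Sox9 24.2% ± 12.3 and 47.8% ± 6.49. Neurog3 together with Cpa1 was found in 3.46% ± 2.31 and 11.8% ± 3.76 of cells, and Ins2 in 0.581% ± 1.16 and 23.8% ± 22.7. The antibody sort, whose gates are not known, can set such shares. Most of the shares that separated the ages no longer did so when reads expected from shared rows and columns were allowed for, as described below.

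Reads of strong genes also appeared in wells that share a row or a column of the plate with a source well. In 28 of 28 gene and plate pairs of hormone and globin genes the share of wells with a read was higher among sharing wells, with medians of 100% and 7.5% (permutation p = 1e-05 in each, the smallest that 100000 resamples can give). The layout of the wells was itself chosen from reads of strong genes, and genes of a plate can share source wells. These p-values are therefore not independent support. The rate, in CPM of the source reads, was 281, 231, 171 and 189 in the E13.25 plates and 979, 1490 and 1356 in E15.25 tip 1, tip 2 and trunk 2. Cpa1 was found in 31% ± 19.4 of mesenchyme-like cells at E13.25 and in 98.6% ± 2.51 at E15.25, a class that should lack it. Exchange predicts 0.743, 0.754 and 0.504 times the Cpa1 reads of these cells in tip 1, tip 2 and trunk 2, but only between 0.072 and 0.277 times those in the E13.25 plates, where most stay without a source. Over the enzyme genes predicted, the median at E13.25 was 0.889 times the reads of mesenchyme-like cells, and 0.398 times their total. Mesenchyme-like cells expected to get more enzyme reads had 4.47 times those of the others, on average over the E13.25 plates (permutation p = 1e-04). This class had median depths between 731132 and 1896875 reads per cluster. When a cell also needed over 3 times the reads expected from its row and column, the share with Cpa1 among all kept cells was 26% ± 9.12 at E13.25 and 41% ± 7.34 at E15.25, and that with Ins2 was 0.581% ± 1.16 and 2.68% ± 1.33. Under this rule the share with Ptf1a was 39.9% ± 6.44 at E15.25, and Neurog3 with Cpa1 was found in 1.73% ± 1.49 at E13.25 and in 0 of 87, 85 and 89 cells at E15.25, which allows up to 3.45%, 3.53% and 3.37% (3 cells of the total) of cells that pass the rule. The rule asks for more reads where the rate is higher, so these limits do not hold for cells that express both genes. Cells with Gcg together with an insulin gene made up 2.62% ± 4.54 at E15.25 before this rule and 0% after it. At E13.25 they made up 0% under both.

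**Figure D2:**
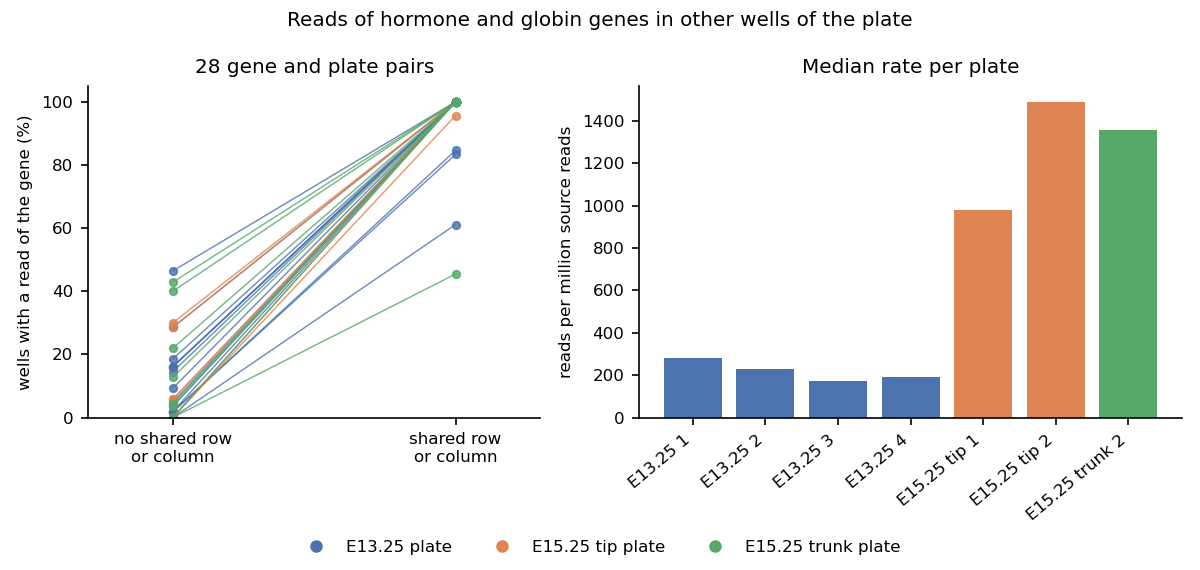
Left, share of wells (%) with a read of a hormone or globin gene among wells without and with a shared row or column with a source well, 1 line per gene and plate pair (28 pairs). Right, median rate of such reads, in CPM of the source reads, in each of the 7 plates, from 171 to 1490.

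**Figure D3:**
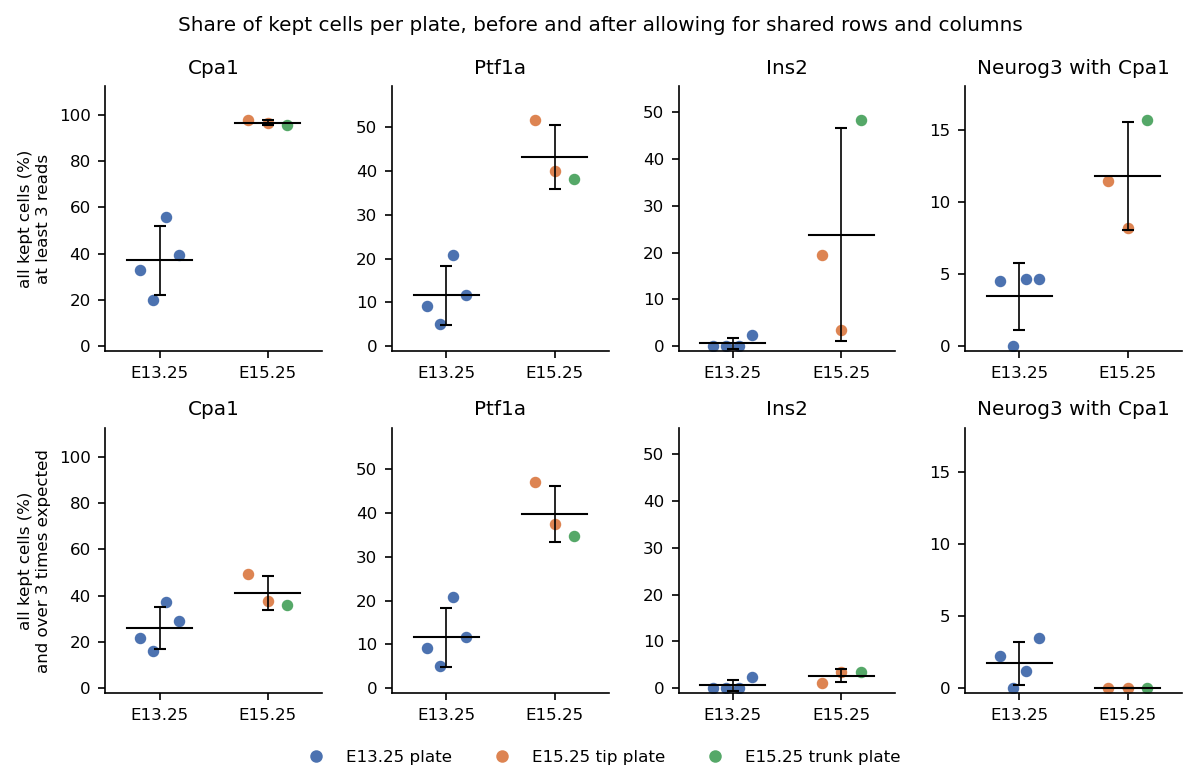
Share of all kept cells (%) per plate with Cpa1, Ptf1a, Ins2 and Neurog3 with Cpa1, 4 E13.25 and 3 E15.25 plates, with means and SD; top, at least 3 reads; bottom, also over 3 times the reads expected from shared rows and columns. Cpa1 at E15.25 averaged 96.6% in the top row and 41% in the bottom row.

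Shares within a class were chosen after seeing the data, and none of those in acinar or tip-like cells passed the threshold after adjustment. Nkx6-1 was found in 76.6% ± 7.54 (n = 4) of them at E13.25 and in 21% ± 6.39 (n = 3) at E15.25 (exact permutation p = 0.0286, adjusted p = 0.171). Ptf1a together with Nkx6-1, the pair that marks progenitors of both tip and trunk fate, was found in 55.1% ± 15.7 and 18.9% ± 5.38 of these cells. Sox9 was found in 95.8% ± 8.33 and 69% ± 8.15, and Pdx1, needed for pancreas formation, in 89.1% ± 18.5 and 41% ± 7.81, whereas Ptf1a was found in 76.6% ± 7.54 and 95.6% ± 1.91. These values were the same under the rule for shared rows and columns. Col3a1, by contrast, went from 67.7% ± 13.8 of acinar or tip-like cells at E15.25 to 0.813% under that rule. In trunk or duct-like cells Neurog3 was found in 37.3% ± 2.65 at E13.25 and 18% ± 4.55 at E15.25 (36.5% and 12.7% under the rule). Cpa1 in trunk or duct-like cells turned its direction, from 37.9% and 89.9% to 23.6% and 12.9% under the rule. The rule asks for more reads where the rate and the reads in other wells are higher, as for Cpa1 at E15.25. The turn can come from the rule alone and does not show fewer cells with Cpa1 at E15.25.

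**Figure D4:**
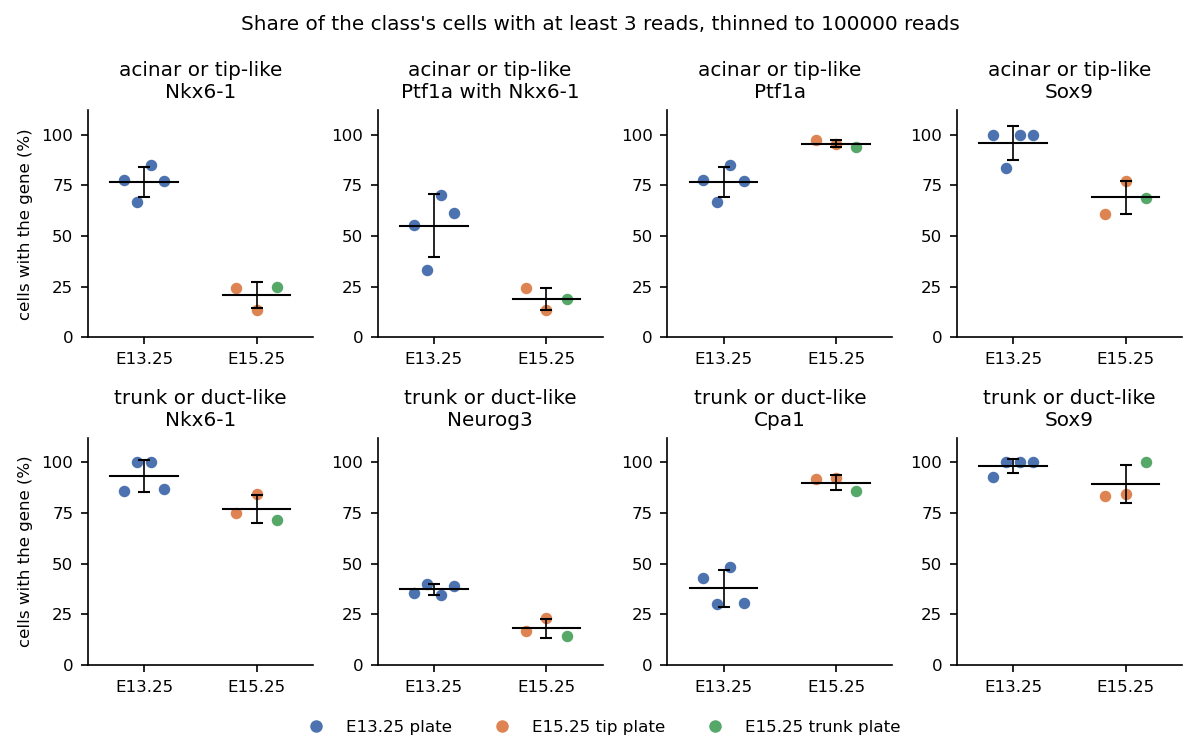
Share of cells (%) with a gene or gene pair among acinar or tip-like cells (top) and trunk or duct-like cells (bottom), per plate, 4 E13.25 and 3 E15.25 plates, with means and SD. Nkx6-1 in acinar or tip-like cells averaged 76.6% at E13.25 and 21% at E15.25.

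Shares of the cell classes did not separate the ages. Acinar or tip-like cells made up 14% ± 6.91 (n = 4) at E13.25 and 30.3% ± 15.1 (n = 3) at E15.25 (exact permutation p = 0.0857, adjusted p = 0.571). Trunk or duct-like cells made up 22.2% ± 9.78 and 14.9% ± 1.02, endocrine-lineage-like cells 8.71% ± 4.18 and 10.3% ± 7.76, and mesenchyme-like cells 41.6% ± 21.6 and 27.2% ± 1.91. Mesothelium-like and erythroid-like cells made up 6.50% ± 2.88 and 5.82% ± 7.76 at E13.25 and 4.16% ± 5.29 and 4.63% ± 3.46 at E15.25. Neural crest or neuron-like cells were seen at E13.25 only (4 cells), and 22 cells of E15.25 in 2 clusters took no name. The antibody sort can set these shares too.

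S phase genes were lower in endocrine-lineage-like cells than in the other epithelial classes, with plate as a block. Against acinar or tip-like cells 18 of 36 S phase genes were lower and none higher (adjusted p = 0.0366 with an estimated correlation), and against trunk or duct-like cells 19 of 36 (adjusted p = 0.0366). Of 42 G2/M phase genes 5 and 2 were lower in these comparisons (adjusted p = 0.17 with an estimated correlation for both). Between acinar or tip-like and trunk or duct-like cells no gene of either list passed the threshold (adjusted p = 0.954 with an estimated correlation for both lists). Without E15.25 tip 2 neither S phase comparison passed (adjusted p = 0.0741 for both with an estimated correlation). Only 2 plates had 10 endocrine-lineage-like cells. Without E13.25 plate 4 or trunk 2 a single such plate was left, with median S phase log2 differences between -3.634 and -3.067. The call cannot be said to hold without either plate. Reads from other wells, which differ between ages, can blur such differences between classes. The clustering left out only the genes of the 2 lists, so other cell cycle genes helped to form the classes. A trunk or duct-like cluster of 21 cells of E13.25 had Mcm10, Kif14 and Knl1 among its leading genes. The difference from trunk or duct-like cells can therefore be built in part by the clustering.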

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

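The tests of where reads in mesenchyme-like cells came from, of immediate early genes, of the batch of reads not aligned and of other splits of the plates were chosen only after the results were seen.

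Digestive enzyme reads appeared in mesenchyme-like cells, which should not make them, at higher levels at E15.25: 12 of 22 measured enzyme genes passed the threshold there. Exchange of reads between wells that share a row or a column, at the rates of the hormone and globin genes, predicts a median over genes of 0.804 times the enzyme reads observed in these cells at E15.25, and 0.637 times their total (1.02, 0.499 and 0.535 in tip 1, tip 2 and trunk 2). Mesenchyme-like cells whose row and column predicted more enzyme reads had 1.71 times those of the cells with fewer predicted, on average over the E15.25 plates (permutation p = 5e-04; by plate 1.5, 2.17 and 1.53, with p = 0.0049, 0.0956 and 0.0087). This position effect argues against free RNA in the sorted suspension as the whole source, and the same ratio of 1.71 argues against expression by the mesenchyme-like cells as the whole source. After the predicted reads were subtracted 3 of the 12 genes (Pnliprp1, Ctrb1 and Clps) still passed. The standard errors grew in all 12, while the log2 changes moved both ways, from 8.09 to 9.20 for Pnliprp1 and from 6.99 to 5.35 for Prss2. The prediction uses 1 median rate per plate, while rates of single genes ran from 1393.7 to 2414.9 in tip 2 and from 974.2 to 1710.3 in trunk 2. The total prediction of 0.637 leaves reads without a source, most of all in these 2 plates. Whether these come from error in the rate, from free RNA or from expression stays open.

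In acinar or tip-like cells the list of immediate early genes had a median log2 change of 2.72, with 5 of 20 past the threshold and the list not called with an estimated correlation (adjusted p = 0.151). In mesenchyme-like cells the median was -0.024, with an SD of 1.19 between the list's members. That fit used all 4 E13.25 plates, while the acinar or tip-like fit used E13.25 plates 3 and 4. The medians argue against handling that acted on every cell of the E15.25 plates alike only as far as these baselines compare. With a term for the batch of reads not aligned the median was 2.62, but age then rests on E13.25 plate 4 alone at the earlier stage, so the batch stays open as a cause. In that fit 4 of the 5 called members lost their call (Btg2 went from 4.07, SE 0.319, to 3.85, SE 0.385). On the 5 plates that hold both classes the difference between the 2 classes was not past the threshold with an estimated correlation (median difference 2.40, 19 of 20 members positive, adjusted p = 0.37). Handling that acts on acinar cells more than on others could still account for it, and age stays among the open explanations.

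The rate of reads from shared rows and columns was between 170.8 and 281.3 CPM at E13.25 and between 979.4 and 1490.2 at E15.25. A batch along this trait cannot be told apart from age. The E13.25 plates 1 to 3 had fewer reads not aligned than E13.25 plate 4 and the E15.25 plates. A library batch marked by this share, which no label names, would overlap with age in part. The titles of plate 4 also differ in the mouse number. A split of the plates by this batch called 4 genes in whole plates, against 141 by age. This argues against the batch of reads not aligned as the whole cause of the calls. With the batch as a term 1 gene was left. The age difference then rests on 1 plate at E13.25, and whether this or the batch ended the calls was not tested. How much the batch adds to each gene stays open. For whole plates 1 of the 35 splits, the real one, called as many as 141 genes, and the highest other called 4. With 35 splits the smallest p is 0.0286, so a chance split of the plates stays unlikely rather than ruled out. The same holds for trunk or duct-like cells (31 genes, highest other 0) and mesenchyme-like cells (142 genes, highest other 4).

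Single plates stood far from the others of E13.25 in 12 of 87 sets of 4 plates tested. Chance gives about 1 in 20, but where the other 3 plates are at 0, as for the shares with Ins2 and Gcg and for Pdia2, any cell or read in 1 plate meets the rule, so that rate does not apply to them. The share of cells with Ins2 was 2.33% in plate 4 and 0% in the others, and Ins2 stood at 2.75 CPM in plate 4 and at most 0.086 CPM elsewhere. The share with Gcg was 1.16% in plate 3 and 0% in the others, and Gcg stood at 2.57 CPM in plate 3 and at most 0.19 CPM elsewhere. Cells with Pecam1 made up 0% in plate 1 and between 1.16% and 1.25% in the others. Cells with Neurog3 and Cpa1 made up 0% in plate 2 and between 4.55% and 4.65% in the others. Endocrine-lineage-like cells made up 2.5% in plate 2 and between 10.2% and 11.6% in the others. Erythroid-like cells made up 17.4% in plate 4 and between 1.25% and 2.33% in the others. In whole plates Pdia2 stood at 0.019 CPM in plate 4 and 0 in the others, Plppr3 at 134 CPM in plate 2 and between 55.2 and 68.4 CPM in the others, Ghrl at 59.8 CPM in plate 4 and at most 0.754 CPM in the others, and Notch1 at 104 CPM in plate 3 and between 81.7 and 83.6 CPM in the others.

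The age change of 7 genes differed between classes by a test of the interaction, made on reads as deposited, so that exchange of reads between wells is not set aside. In acinar or tip-like against mesenchyme-like cells the difference in log2 change was 3.67 for Col3a1, 3.98 for Col6a1, 3.46 for Sparcl1 and -6.35 for Fscn1 (adjusted p = 0.0471 for each, edgeR). In trunk or duct-like against mesenchyme-like cells it was -5.01 for Clip3 and -2.57 for Igfbp4 (adjusted p = 0.0116 for both) and -6.06 for Clps (adjusted p = 0.0404). The value for Clps comes from its rise of 6.89 in mesenchyme-like cells, where exchange predicts 1.03, 0.47 and 0.804 times its reads in E15.25 tip 1, tip 2 and trunk 2. The share of acinar or tip-like cells with Col3a1 at E15.25 went from 67.7% to 0.813% under the rule for shared rows and columns. With the expected reads subtracted Clps still passed in mesenchyme-like cells (log2 change 7.25, SE 1.2, adjusted p = 0.0478), and the interaction was not tested on subtracted reads. How much of either difference is expression is open. Between acinar or tip-like and trunk or duct-like cells 0 of 17761 genes passed this edgeR test.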

How the results depend on the processing

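The alternatives with reads of shared rows and columns, with the term for reads not aligned, with shares within a class, and every value for mesenchyme-like cells were chosen after seeing the data. Over all settings but those that leave out a plate, 1225 of 1506 values of named genes stayed on their side of the threshold, 243 lost their call, 38 gained one and none reversed. With 1 plate left out, 488 of 1124 stayed, 636 lost their call and none reversed. Of the values with the term for reads not aligned 113 of 153 lost their call and none reversed. DESeq2 size factors and at least 3000 genes per cell left every count of genes within 1.5 times. Some genes given above as not past the threshold passed in another setting. These were Ptf1a, Cpa1, Spp1 and Neurog3 in whole plates, and Nkx6-1 and Sox9 in acinar or tip-like and in trunk or duct-like cells.

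In the order whole plates by age, tip against E13.25, tip against trunk, trunk against E13.25, acinar or tip-like, trunk or duct-like, endocrine-lineage-like and mesenchyme-like cells by age, the counts were 141, 19, 0, 10, 110, 31, 1 and 142. The DESeq2 Wald test gave 2154, 2219, 338, 1263, 1788, 747, 506 and 1574. With each cell scaled to the same total the counts that moved were 566, 88, 16, 192, 78, 2 and 374 (tip against trunk stayed at 0). Without a filter on low counts tip against E13.25 gave 55, trunk against E13.25 26, acinar or tip-like cells 588 and endocrine-lineage-like cells 218. Without the 5% of cells with the most genes whole plates gave 63, tip against E13.25 12, trunk against E13.25 4, acinar or tip-like cells 14 and endocrine-lineage-like cells 3. In 3 groups of plates the age comparison gave 25, and in 2 groups alone trunk against E13.25 gave 2. With at least 5 cells per plate acinar or tip-like cells gave 270. With expected reads subtracted endocrine-lineage-like cells gave 0 and mesenchyme-like cells 89. The term for reads not aligned left 1, 30, 0, 0 and 0 in whole plates and in acinar or tip-like, trunk or duct-like, endocrine-lineage-like and mesenchyme-like cells. The cause was not tested for these changes. With 1 plate left out the counts ran from 11 (without E15.25 tip 1) to 63 in whole plates, 2 to 202 (without tip 1) for tip against E13.25, 0 to 0 for tip against trunk, 3 to 6 for trunk against E13.25, 1 (without tip 1) to 31 in acinar or tip-like, 0 (without tip 1 or trunk 2) to 14 in trunk or duct-like, 0 to 0 in endocrine-lineage-like and 0 (without trunk 2) to 58 in mesenchyme-like cells. Tip against trunk without trunk 2 could not be fitted.

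Of the lists called by camera with the preset correlation (12, 12, 8, 12, 11, 13, 11 and 14 in the same order), the estimated correlation left 1, 1, 0, 1, 1, 1, 0 and 0, and fry 7, 3, 0, 2, 6, 8 and 4 in the first 7. Shares that separated the ages numbered 7 of 21, and between 7 and 11 (without tip 1) with a plate left out. Under the rule of 3 times the expected reads they numbered 1. That rule asks for more reads at E15.25, and under it the share with Neurog3 and Cpa1 reversed, to a difference of -1.73 percentage points. Class shares that separated the ages numbered 0, between 0 and 1 with a plate left out, and 2 at a resolution of 0.5. For the cell cycle lists 4 of 6 camera tests with the preset correlation passed with the plate block and 5 without the replicate block. With an estimated correlation the 2 S phase tests against endocrine-lineage-like cells passed (adjusted p = 0.0366 for both) and no G2/M phase test did (0.17 against these cells). Without E15.25 tip 2 the 2 S phase tests did not pass (adjusted p = 0.0741 for both with an estimated correlation). Nor can the calls be said to hold without E13.25 plate 4 or trunk 2, which each leave a single endocrine-lineage-like plate. On simulated data 2-fold changes were recovered in 0% of changed genes in whole plates and in at most 1.5% in any comparison.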

Other observations

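The comparison in mesenchyme-like cells was chosen after seeing the data. Between the ages 142 of 15388 genes differed in them, 101 higher and 41 lower at E15.25 (edgeR, 4 against 3 plates). The DESeq2 Wald test called 767 higher and 807 lower. In edgeR with the reads expected from shared rows and columns subtracted 89 differed, 63 higher and 26 lower. Of the 101 higher genes 12 are digestive enzyme genes, whose reads exchange between wells can bring into these cells. Genes of other cell types were higher too: Rbpjl, Krt18 and Spp1 (log2 changes 5.17, 5.17 and 4.84) and Iapp (3 reads at E13.25, ratio 1830, counting interval 625 to 8860). All 4 lost their call with the expected reads subtracted, at log2 changes of 5.04, 5.39, 6.15 and 8.51, so their source is open. In the mesenchyme list 6 of 24 measured genes rose (12 rose and 2 fell adjusted over the list alone; adjusted p = 0.0858 with an estimated correlation). The collagen gene Col3a1 rose from 2816 ± 271 CPM (n = 4) to 7989 ± 944 CPM (n = 3), Col6a1 from 478 ± 86.8 to 1610 ± 129 CPM and Sparc from 1976 ± 259 to 5151 ± 312 CPM. The proteoglycan gene Dcn rose from 169 ± 72.4 to 2154 ± 746 CPM. Ldha, of the glycolysis and hypoxia list, rose by 1.98 on the log2 scale, and Kank4, Cxcl10 and St6galnac2 rose by 8.69, 8.60 and 7.70. Arsj had 2 reads at E13.25 and a ratio of 2930 (counting interval 810 to 24200).

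Other genes were lower at E15.25. Hmga2, a chromatin factor of embryonic cells, had 303 ± 104 CPM at E13.25 and 6.49 ± 4.63 CPM at E15.25 (adjusted p = 0.0126). Nnat had a log2 change of -4.45, Sox11 one of -2.44 and Sox4 one of -2.08. Kif26b, Sbk1, Nav2, Syt6 and Gsta4 had log2 changes between -3.97 and -2.45. Snx31 had 0 reads at E15.25 and was at least 514-fold lower there. The count of 142 was 43, 58, 38 and 43 without E13.25 plates 1 to 4, 35, 47 and 0 without E15.25 tip 1, tip 2 and trunk 2, and 0 with the term for reads not aligned. On simulated data the fit recovered 22.4% of 4-fold and 33.3% of 8-fold changes.

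Mesenchyme-like cells of E15.25 fell into a cluster of 48 cells, of which 23 and 24 came from tip 1 and tip 2, and one of 23 cells, of which 22 came from trunk 2. The second cluster was led by Acta2, Mgp and Cdc42ep2, and the first by Rtl3, Abcc9 and Tspan18. The acinar or tip-like cluster of 37 cells led by Cela2a and Cpb1 took 28 cells from tip 1. An E15.25 cluster without a name held 13 cells, all of tip 2, and another 9 cells, all of trunk 2. At E13.25 a mesenchyme-like cluster of 20 cells was led by the cell cycle genes Aspm, Kif2c and Top2a. These clusters and their leading genes come from clustering settings set after the data were seen. A sort or a plate effect and a regional difference cannot be told apart here, since tip and trunk differ in plate.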
